A study of Homo sapiens with 8 samples.

How the data were processed

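The study collected total RNA from 2 human glioblastoma cell lines, A172 and U87MG, grown in serum-containing medium, and sequenced it as RNA-seq libraries. The 8 libraries fall into 4 groups of 2, taken from the sample titles. In each line, one group received gamitrinib at 5 µM and the other served as the vehicle control (DMSO), both for 72 h.

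Per the submitters' processing notes, the work named FastQC 0.11.5, Trim Galore 0.6.5 and featureCounts 2.0.2 with the GRCh38 build. The aligner, the annotation release and the strand setting of the counting are not given in the sources used here. The one table of the series has the columns that featureCounts writes (feature name, exon coordinates, strand and length), per the file headers. Further columns follow, and their values were not read.

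The 8 columns of per-sample values were not used. Their names are a letter with a number and match no title, description or other label of any sample. Assigning them to samples from their order in the table, or from the values they hold, would have meant guessing which libraries were treated. For that reason no depth per sample, no expression level and no comparison between groups is given. The differential expression tests and gene-list tests planned before the data were examined were not run, and neither were their alternatives. The precision that the depth of each library would give is likewise not analysed here.

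What was analysed is the feature annotation that the counting rested on. Of 59430 lines after the header, 3 had broken fields. These 3 lines hold the single entry of ANK2, split across them, and the entry was left out. Its longest coordinate field holds 32759 characters, close to the 32767 that a spreadsheet cell can hold. The remaining 59427 features were read with Python 3.11.15, pandas 2.3.3 and NumPy 2.4.6. Exons of each feature were merged, and the merged length in bases was compared with the deposited length, for which the header gives no unit. The merging step was tested on 200 simulated features and recovered all 200 lengths. Each merged exonic base was then scored for whether exons of another feature covered it, on either strand, on the opposite strand or on the same strand. A gene was counted as sharing sequence where at least 10% of its exonic bases were covered in this way.

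Positions were compared with GENCODE release 29, which is also on GRCh38, by gene name. The 37 gene lists were fixed before the data were examined, as was the rule for named genes. That rule ranks genes by expression change, so only the part that names the HSP90 family, ATF4, DDIT3, TFAM, PPARGC1A, CDKN1A and MKI67 whatever their values could be applied. Other genes named here were chosen after their annotation was seen. The limit of 10% and its alternatives were chosen after seeing the data.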

Results

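The series addresses how glioma cells respond to gamitrinib, an HSP90 inhibitor directed to mitochondria, where it acts on the chaperone TRAP1. Total RNA was sequenced from A172 and U87MG, both established human glioblastoma lines, after 72 h with 5 µM gamitrinib or with the DMSO vehicle. The 8 libraries form 4 groups with 2 libraries each. The labels do not say whether the 2 libraries of a group came from separate cultures.

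The design implies a treated against control comparison in each line and a test of whether the 2 lines responded differently. It also implies a comparison of the DMSO controls of the 2 lines with each other. None of these comparisons was made, because the 8 columns of per-sample values carry names that match no sample label. No gene is therefore reported here as higher, lower or unchanged. The measurements below describe the gene models on which the reads were counted, which are the same for every library.

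The count table covered 59427 readable features, with a median exonic length of 1156 bases. The deposited length equalled the merged length of the listed exons in all 59427. By name, 37726 features had a counterpart in GENCODE release 29, and 37534 of these (99.5%) lay on the same chromosome and strand. Of the 37726, 37359 (99.0%) also overlapped their counterpart in position. Exonic length was identical for 21931 (58.1%) and within 10% for 33380 (88.5%), so the gene models were not those of release 29 throughout. Across the table, 11249 features (18.9%) had at least 10% of their exonic bases covered by exons of another feature.

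TRAP1, the mitochondrial HSP90 paralog, was annotated on the minus strand of chromosome 16 from 3651639 to 3717553 (GRCh38). Of its 5183 exonic bases, 1477 (28.5%) were shared, and all 1477 were covered by exons on the opposite strand. Within these 1477, 65 (1.25% of the exonic bases) were also covered by exons of another feature on the same strand. Counting either strand, the cytosolic paralogs had less shared sequence. HSP90AA1, the stress-inducible form, lay on chromosome 14 from 102080742 to 102139699, with 197 of 5097 exonic bases (3.87%) shared. HSP90AB1, the constitutive form, lay on chromosome 6 from 44246166 to 44253888, and none of its 2980 exonic bases was shared. HSP90B1, which encodes the endoplasmic reticulum chaperone GRP94, lay on chromosome 12 from 103930107 to 103953931, with 1041 of 13092 exonic bases (7.95%) shared.

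DDIT3, which encodes the stress-response transcription factor CHOP, lay on chromosome 12 from 57516588 to 57521737. Of its 1307 exonic bases, 518 (39.6%) were shared, 413 (31.6%) on the opposite strand and 105 (8.03%) on the same strand. ATF4, the transcription factor upstream of DDIT3, lay on chromosome 22 from 39519695 to 39522683 and shared none of its 2613 exonic bases. Of the 45 genes listed for the integrated stress response, 9 passed the 10% limit. Counting features on the opposite strand only, 7 of the 45 passed it, and counting those on the same strand only, 3 of the 45. With features on either strand, 4 of 30 genes of the unfolded protein response of the endoplasmic reticulum passed the limit, and 6 of 27 genes of the cytosolic heat shock response. On the same strand alone, these numbers were 0 of 30 and 1 of 27.

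The lists for nuclear-encoded mitochondrial proteins lay on both sides of the 18.9% of the whole table. They also lay on both sides of the 21.5% found over the genes of all lists. No list was tested against either share. The lists also differed in median exonic length, from 2324 bases for complexes II to V to 6047.5 for fission, fusion and mitophagy. The median was 5032 for chaperones and proteases and 1156 over the whole table. Whether length bears on the shares was not tested. The number was 16 of 37 complex I subunits (43.2%), 28 of 75 mitochondrial ribosomal proteins (37.3%), 10 of 27 mitochondrial chaperones and proteases (37.0%) and 13 of 39 subunits of complexes II to V (33.3%). It was 9 of 26 for mitochondrial import (34.6%), 7 of 25 for the TCA cycle (28.0%) and 5 of 26 for mitochondrial biogenesis and mtDNA maintenance (19.2%). The share was lower for fatty acid oxidation, with 3 of 20 (15%), and for fission, fusion and mitophagy, with 2 of 20 (10.0%). These numbers, like the 18.9% and the 21.5%, count features on either strand. On the same strand alone, 83 of the 1009 features matched by the lists passed the limit. The same-strand share of the whole table was not computed. With features on the same strand alone, 8 of 37 complex I subunits and 12 of 75 mitochondrial ribosomal proteins passed the limit. So did 3 of 27 chaperones and proteases, 6 of 39 subunits of complexes II to V and 4 of 26 import genes. The number was 2 of 25 for the TCA cycle and 2 of 26 for biogenesis and mtDNA maintenance. Fatty acid oxidation and fission, fusion and mitophagy each had 0 of 20. TFAM, which packages mtDNA, lay on chromosome 10 from 58385345 to 58399220 and shared none of its 5282 exonic bases. PPARGC1A, the coactivator PGC-1α, lay on chromosome 4 from 23755041 to 23904089 and shared none of its 10870.

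The 13 protein-coding genes of the mitochondrial genome were all present as features. All shared bases in these 13 genes were shared with features on the same strand. MT-ATP8 shared 46 of its 207 bases (22.2%), MT-ATP6 shared 47 of 681 (6.9%) and MT-ND4L shared 7 of 297 (2.36%). MT-ND6, the only one of the 13 on the minus strand, shared none of its 525 bases.

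Counting either strand, the cell-cycle lists were uneven, and they were not tested against each other. Over the limit were 7 of 22 G1 cyclins, CDKs and inhibitors (31.8%) and 7 of 44 DNA replication genes (15.9%). So were 5 of 38 mitosis genes (13.2%) and 3 of 47 replication-dependent histones (6.38%). With features on the same strand alone, the numbers were 1 of 22, 2 of 44, 3 of 38 and 3 of 47 in that order. MKI67, which encodes the proliferation antigen Ki-67, lay on chromosome 10 from 128096659 to 128126423 and shared none of its 12845 exonic bases. CDKN1A, which encodes the CDK inhibitor p21, lay on chromosome 6 from 36676460 to 36687337, with 146 of 2996 exonic bases (4.87%) covered on the opposite strand. Among the p53 targets, 6 of 30 passed the limit on either strand and 3 of 30 on the same strand alone. All values in this section are properties of the annotation, so they carry no replicate error, and they give no information on expression in either cell line.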

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

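The alternatives for normalization, filtering, testing and left-out libraries planned before the data were examined were not run, because the count columns were not matched to samples. No paired analysis was possible because the count columns match no sample label, so their replicate numbers are unknown. The alternatives below were all chosen after seeing the data. The 1010 list genes matched 1009 different features, so not every list gene had a feature of its own. Genes found by their current symbol cannot share a feature, so the double match came through an alternative symbol. That match was not checked further. Of the 1009 features, 217 shared at least 10% of their exonic bases with another feature on either strand. The number was 82 with a limit of 25%, 489 with any shared base, and 83 when features on the same strand alone were counted, as counting with strand would do. With current symbols alone, 1007 list genes were found, and 3 were found only through an alternative symbol.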

Other observations

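Some genes of the lists fixed in advance shared most of their exonic bases with other features. The genes named here were chosen after their annotation was seen. TOMM6, a small subunit of the mitochondrial import receptor complex, shared all 637 of its exonic bases on the same strand. MRPL53, a mitochondrial ribosomal protein, shared 681 of 685 bases. SRXN1, which encodes sulfiredoxin, shared 2292 of 2528 bases, and CYP51A1, a cholesterol synthesis enzyme, shared 2982 of 3529. NUSAP1, a mitotic spindle protein, shared 2938 of 3608. A smaller part was shared by HSPE1 and HSPD1. These genes, which encode the mitochondrial chaperonin pair HSP10 and HSP60, lie on opposite strands of chromosome 2, from 197500140 to 197503449 for HSPE1 and from 197486584 to 197516737 for HSPD1. HSPE1 shared 327 of 1823 bases, 135 with features on the opposite strand and 192 with features on the same strand. HSPD1 shared 135 of 7629, all with features on the opposite strand.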
